A study of Homo sapiens with 8 samples.

How the data were processed

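RNA-seq and ribosome profiling (Ribo-seq) libraries came from MDA-MB-231 cells given either a control siRNA or an siRNA against ADAR1. Per the labels' protocols, cleared lysates were run on sucrose gradients, RNA was size-selected on denaturing gels, and footprint-sized RNA gave the Ribo-seq libraries while longer fragments gave the RNA-seq libraries, which the labels call Input. Both kinds were made by adapter ligation at both ends and PCR, and sequenced on an Illumina platform. Both assays therefore measured short RNA fragments, and no molecular identifiers are mentioned in the labels. A ribonuclease, the siRNA sequence and the time after transfection are not given in the sources used here.

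The submitters' processing notes name cutadapt, Bowtie2, STAR and featureCounts, and the genome build GRCh38 (hg38). Their versions, settings, order and roles are not given in the sources used here, nor is the strand setting of the counting. The deposited table of the whole series lists 19892 genes by NCBI gene number, with 3 kinds of values for each library. The first is an estimated count per gene, deposited without normalization. Between 87.0% and 90.1% of these values per library were whole numbers. How the fractional values arose, and whether reads were shared out between genes, is not given in the sources used here. The second is TPM as the authors deposited it, a level per transcript length and library, which had the same sum in each library. The third is the authors' deposited translational efficiency, a ratio of the Ribo-seq TPM to the Input TPM; in each of the 4 columns, 100% of its values equalled the ratio of the 2 libraries with the same siRNA and replicate number, within rounding. All columns of the table were used. Gene symbols were looked up by gene number, and 19669 of the 19892 numbers matched; the other 223 kept their number. Coordinates are those of the RefSeq gene table for GRCh38.p14, 1-based.

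Each of the 4 groups (control siRNA or ADAR1 siRNA, Input or Ribo-seq) held 2 libraries, grouped by their titles. Total estimated counts ran from 15732757 to 17153716 per Input library and from 10492223 to 14875465 per Ribo-seq library. No pair of replicates agreed within sampling noise: the mean Poisson chi-square per gene was 1.92 and 19.0 for the control and ADAR1 siRNA Input pairs, and 7.38 and 35.8 for the Ribo-seq pairs. All 8 libraries were therefore kept as separate samples.

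Estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, genes with low counts were removed with filterByExpr, and quasi-likelihood tests (two-sided) were adjusted by the Benjamini-Hochberg method at a false discovery rate of 0.05. RNA changes were tested over the 4 Input libraries, footprint changes over the 4 Ribo-seq libraries, and translational efficiency changes over all 8 libraries as the interaction of assay and siRNA, without a replicate block. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-F statistic. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.333, so single genes rest on the model's shared estimate of the spread. Depth, dispersion and the number of libraries together set what could be called. Counts were simulated with the mean per gene of each assay, the library sizes, and a dispersion per gene that both siRNAs shared. Changes were planted only in genes with a mean count of at least 50. A 2-fold change was called for 90% of 50 changed genes in the RNA test, 78% in the Ribo-seq test and 46% in the translational efficiency test. For a 1.5-fold change these shares were 54%, 30% and 6%, and for a 4-fold change 100%, 100% and 86%. The simulation left out the larger spread between the ADAR1 siRNA replicates, so these shares may not hold for the data. Of the calls made on simulated counts, 6.01% were false in the RNA test, 12.5% in the Ribo-seq test and 15.1% in the translational efficiency test, more than the 5% the threshold names.

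The list of genes named in the text follows a rule fixed before the data were examined, as were the main tests, the 30 gene lists and most of the alternatives. For each of the 3 comparisons the rule takes ADAR, then the 6 genes with the largest rise and the 6 with the largest fall among those with an adjusted p under 0.05, a mean count of at least 50 and groups that do not overlap. It then takes the 3 members of smallest p from each list that passed its test, and from the interferon-stimulated, double-stranded RNA sensing, integrated stress response and cytosolic ribosomal protein lists in any case. Genes named outside the rule are said to be so where they appear, and some results that the rule would name are not reported here, though counts include them.

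Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and adjusted over the 28 lists with at least 5 tested members. The lists were the ADAR family, interferon-stimulated genes, sensors of double-stranded RNA, NF-kB targets and inflammatory cytokines, ATF4 targets of the integrated stress response, endoplasmic reticulum (ER) chaperones of the unfolded protein response, cytosolic ribosomal proteins, translation factors, mitochondrial ribosomal proteins, nuclear-encoded respiratory chain subunits, mRNAs of the mitochondrial genome, G1/S genes, G2/M genes, replication-dependent histones, p53 targets and apoptosis, mesenchymal and matrix genes, YAP and TEAD targets, sterol synthesis, glycolysis and hypoxia, the transcription machinery, splicing factors and RNA-binding proteins, the N6-methyladenosine (m6A) machinery, the microRNA machinery, known ADAR recoding substrates, and markers of luminal epithelial, basal or myoepithelial, immune and endothelial cells. Nuclear noncoding RNAs and noncoding hosts of small nucleolar RNAs made up the remaining lists, which had too few members among the genes analysed to be tested. The list of sensors of double-stranded RNA, called the double-stranded RNA sensing list below, also held adaptors, kinases and transcription factors of their signalling. List medians are medians of log2 CPM differences. They were first taken from the edgeR fold changes and were moved to the log2 CPM values that camera tests after first results had been seen. In a simulation over 28 lists of randomly drawn genes, a list shifted by 0.5 on the log2 scale was called and 0 unshifted lists were. Its genes were simulated independently of each other, so it cannot show how often lists of co-regulated genes are called falsely.

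Alternatives were RLE and upper-quartile scaling, no filter on low counts, a mean count of at least 50, DESeq2 1.42.0, limma-voom, the replicate number as a block, 1 fit over all 8 libraries, camera with an estimated correlation, fry, and each library left out in turn. Leaving out both ADAR1 siRNA libraries of a replicate number, and 1 fit over all 8 libraries for the gene lists, were added after the data were examined. Python with pandas and matplotlib read the table and drew the plots. Because no genome sequence was used, no GC content was computed for any gene, and A-to-I editing, splicing and the position of footprints along transcripts were not analysed here.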

Results

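Messenger RNA and ribosome-protected fragments were measured in MDA-MB-231 cells, an established line of triple-negative breast cancer, after a control siRNA or an siRNA against ADAR1. ADAR1, encoded by ADAR, is the enzyme that converts adenosine to inosine in double-stranded RNA. The series title asks about the role of ADAR1 in the transcriptional output of cancer cells, and the design sets ADAR1 siRNA against control siRNA in each assay. Each of the 4 groups held 2 libraries, 8 in all. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Input libraries held 15732757 to 17153716 estimated counts, control Ribo-seq libraries 11975081 and 10492223, and ADAR1 siRNA Ribo-seq libraries 14646868 and 14875465. Transcripts of the mitochondrial genome took 4.03% to 4.74% of counts in Input and 1.19% to 1.47% in Ribo-seq.

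The target itself was examined before any other gene. ADAR (NCBI gene 103; GRCh38.p14 chromosome 1, 154582057 to 154627997) stood at 108.2 ± 2.79 TPM in control Input and 22.7 ± 11.1 TPM in ADAR1 siRNA Input (mean ± SD, n = 2 each). Replicate 1 of the ADAR1 siRNA held 13.7% of the control mean and replicate 2 held 28.3%. In Ribo-seq ADAR stood at 19.7 ± 0.803 TPM with control siRNA and 4.98 ± 4.85 TPM with ADAR1 siRNA, where replicate 1 held 7.87% and replicate 2 held 42.7% of the control mean. All 4 ADAR1 siRNA libraries lay below all controls of their assay, as their labels say. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change was -2.26 ± 0.32 (SE) in RNA, with an adjusted p of 0.0527 that just missed the threshold, and -2.04 ± 0.47 in Ribo-seq, with an adjusted p of 0.0485. Translational efficiency of ADAR did not change detectably (log2 0.25 ± 0.68, edgeR adjusted p = 0.867). The RNA call depended on single libraries: without ADAR1 siRNA Input replicate 1 the log2 fold change was -1.81 and without replicate 2 it was -2.94, and both then passed. In Ribo-seq the value was -1.33 without replicate 1 and -3.50 without replicate 2. The authors' deposited table gives ADAR a translational efficiency of 0.180 and 0.184 in the controls, 0.105 in ADAR1 siRNA replicate 1 and 0.275 in replicate 2.

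**Figure D1:**
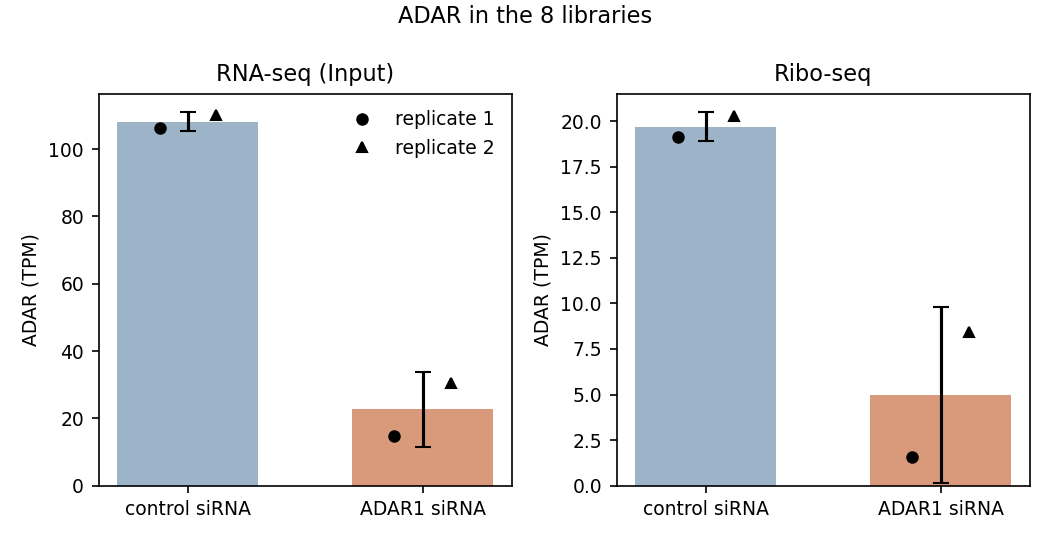
ADAR level in TPM (vertical axes, from 0) by siRNA, in RNA-seq on the left and Ribo-seq on the right; bars are means, error bars SD over 2 libraries, and points the single libraries. In Input the ADAR1 siRNA mean is 22.7 TPM against 108.2 TPM in controls, and in both assays replicate 2 of the ADAR1 siRNA lies above replicate 1.

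RNA levels were compared first. Folds in this paragraph are edgeR estimates from TMM-scaled counts, so they can differ from the ratios of the TPM means beside them. H1-2, a linker histone, rose 2.28-fold from 92.7 ± 2.81 to 214.4 ± 24.1 TPM. GADD45A, induced by DNA damage and other stress, rose 2.17-fold from 44.5 ± 1.49 to 97.8 ± 18.5 TPM. CST4, a secreted cysteine protease inhibitor, fell 2.68-fold from 156.7 ± 7.19 to 58.9 ± 5.52 TPM, and ISG15, an interferon-induced ubiquitin-like protein, fell 2.13-fold from 123.4 ± 0.272 to 58.7 ± 11.6 TPM (mean ± SD, n = 2 libraries per group).

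Of 12644 genes tested in RNA, 32 changed at an edgeR adjusted p under the threshold, 10 of them higher and 22 lower, and 3202 had an unadjusted p under 0.05. The other genes with the largest rises were COMMD3-BMI1 (log2 1.33 ± 0.13), TNFSF15 (0.96 ± 0.11), HDAC9 (0.92 ± 0.11) and TFPI (0.88 ± 0.07). TNFSF15 is a cytokine of the TNF family, HDAC9 a histone deacetylase and TFPI an inhibitor of coagulation. COMMD3-BMI1 is a readthrough transcript whose reads overlap COMMD3 and BMI1, so its own value is uncertain. The counts of the 3 genes summed differed by 0.26 on the log2 scale, and BMI1 held most of them. BMI1 stayed near level (2218 and 2412 counts in control Input, 2225 and 2195 with ADAR1 siRNA). COMMD3 did not fall (499 and 539 against 616 and 580). The other large falls were ENTPD3 (-1.30 ± 0.16), an ectonucleotidase, SLCO4A1 (-1.22 ± 0.10), an organic anion transporter, G0S2 (-1.10 ± 0.12), an inhibitor of lipolysis, and FOXQ1 (-1.09 ± 0.10), a forkhead transcription factor. Adjusted p-values of these 12 genes by edgeR lay between 0.0346 and 0.0488. With 1 library left in a group, the spread came from the other pair, and the lone library was assumed to vary like it. Without control Input replicate 1 or replicate 2 it was 0 (edgeR, with 1055 and 958 genes at an unadjusted p under 0.05, 0 by limma-voom and 12 by DESeq2 in either case), whereas without ADAR1 siRNA Input replicate 1 it was 4119 and without replicate 2 it was 5420. All 12 of these genes lost their call without either control library and 0 without either ADAR1 siRNA library. The ADAR1 siRNA and control libraries did not overlap for 58.2% of tested genes, against 33.3% by chance if all libraries varied alike. The ADAR1 siRNA pair lay further apart than the controls (SD of log2 differences 0.304 against 0.145). Unequal spread raises the share that chance gives, so the size of the excess is not known.

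Of the 28 lists tested in RNA, 5 shifted with camera's preset correlation (9 without ADAR1 siRNA Input replicate 1, 8 without replicate 2), and none did with an estimated correlation. Replication-dependent histones stood highest (median log2 0.78, 15 of 15 tested members above 0, camera adjusted p = 7.74e-06, adjusted p = 0.885 with an estimated correlation). Of them H1-2 rose among all genes and 6 rose adjusted over the list alone. H2AC6 (0.84 ± 0.18) and H2AC18 (1.09 ± 0.30) had edgeR adjusted p-values of 0.0765 and 0.102 over all genes. Levels in control Input were low beside those in control Ribo-seq: 15.9 against 2659 TPM for H2AC18, 35.2 against 1301 for H2AC6 and 92.7 against 1862 for H1-2. Only 15 histones passed the count filter in Input, against 38 in Ribo-seq, where the median was 0.02. How fully Input captured histone transcripts was not tested. The ATF4 targets of the integrated stress response were shifted up (median 0.26, 29 of 34 above 0, camera adjusted p = 0.000321, adjusted p = 0.903 with an estimated correlation), with medians of 0.17 without ADAR1 siRNA Input replicate 1 and 0.41 without replicate 2. None of these 34 passed among all genes and 10 rose adjusted over the list alone, among them DDIT3 (0.86 ± 0.14), which encodes the transcription factor CHOP, the phosphatase subunit gene PPP1R15A (0.36 ± 0.06) and asparagine synthetase ASNS (0.97 ± 0.18). NF-kB targets and inflammatory cytokines were shifted up (median 0.53, 23 of 28 above 0, camera adjusted p = 0.00377, adjusted p = 0.918 with an estimated correlation). No member passed among all genes and 1 did adjusted over the list alone; IL1A, the gene of interleukin 1 alpha, had a log2 fold change of 3.48 ± 0.59, CXCL1 of 1.15 ± 0.33 and REL of 0.31 ± 0.08. The list lost its call without ADAR1 siRNA Input replicate 1 (camera adjusted p = 0.181), where its median was 0.23; without replicate 2 the median was 1.16.

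The interferon-stimulated list was shifted down in RNA (median log2 -0.26, 45 of 65 below 0, camera adjusted p = 0.00376, adjusted p = 0.918 with an estimated correlation). ISG15 alone fell among all genes; adjusted over the list alone 14 fell and 1 rose. ISG20, an interferon-induced exonuclease, had a log2 fold change of -1.36 ± 0.22 and OASL, an oligoadenylate synthetase-like protein, of -0.96 ± 0.17 (edgeR adjusted p = 0.0647 and 0.0672). The list median stood at -0.02 in ADAR1 siRNA Input replicate 1 and at -0.31 in replicate 2. Without replicate 2 it was -0.02 (camera adjusted p = 0.461), and without control Input replicate 1 it was -0.12. Luminal epithelial markers were also lower (median -0.48, 13 of 15 below 0, camera adjusted p = 0.0191, adjusted p = 0.903 with an estimated correlation); 0 passed among all genes by edgeR, where 5 had an unadjusted p under 0.05, and 3 fell adjusted over the list alone. Among them were SPDEF (-1.31 ± 0.18), an epithelial transcription factor, the keratin gene KRT19 (-0.63 ± 0.09) and the tight junction gene CLDN4 (-0.89 ± 0.19). Its median was -0.74 without ADAR1 siRNA Input replicate 1. Without replicate 2 its camera adjusted p was 0.283, and with a mean count of at least 50 it was 0.135.

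The other 23 lists did not shift in RNA, with camera adjusted p-values from 0.131 to 0.816. The double-stranded RNA sensing list had a median of -0.10, with OAS3 at -0.35 ± 0.07, IRF7 at -0.55 ± 0.16 and IRF3 at -0.30 ± 0.08. Cytosolic ribosomal proteins had a median of 0.04, with RPL9, RPS3A and RPS12 each at 0.25. Medians of the remaining lists were -0.09 for the ADAR family, -0.11 for glycolysis and hypoxia, 0.10 for YAP and TEAD targets, 0.13 for the m6A machinery, 0.08 for translation factors, 0.06 for sterol synthesis, -0.04 for respiratory chain subunits, -0.07 for the mitochondrial genome, 0.04 for p53 targets, -0.05 for mitochondrial ribosomal proteins, 0.06 for G2/M genes, 0.01 for G1/S genes, 0.07 for mesenchymal and matrix genes, 0.05 for ER chaperones, -0.04 for the microRNA machinery, 0.02 for known recoding substrates, -0.02 for splicing factors and 0.01 for the transcription machinery. Markers of other cells had medians of -0.50 (endothelial, 5 genes), -0.12 (immune, 9 genes) and -0.15 (basal or myoepithelial, 10 genes, whose mean was 0.08). The G1/S mean was slightly below 0 where its median was above it.

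Among ribosome footprints, those of several chemokine genes rose and those of several interferon-stimulated genes fell. The folds given next are again edgeR estimates from scaled counts and not ratios of the TPM means beside them. CXCL8, which encodes interleukin 8, rose 3.45-fold from 98.5 ± 0.552 to 314.4 ± 71.7 TPM. CXCL3 rose 6.44-fold from 2.14 ± 0.684 to 12.9 ± 3.43 TPM. IFIT1, an interferon-induced protein that binds viral RNA, fell 2.93-fold from 20.7 ± 1.61 to 6.52 ± 0.0778 TPM. OASL fell 2.80-fold from 33.2 ± 4.22 to 11.4 ± 2.84 TPM, and CASP1, the inflammatory caspase, fell 3.76-fold from 4.17 ± 0.141 to 1.05 ± 0.705 TPM (mean ± SD, n = 2 libraries per group).

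Of 12000 genes tested in Ribo-seq, 425 changed by edgeR, 225 higher and 200 lower, and 2878 had an unadjusted p under 0.05. With upper-quartile scaling the split was 311 higher and 176 lower, and with DESeq2 391 higher and 587 lower. Other large rises were those of CCL2 (log2 2.42 ± 0.53), a monocyte chemokine, IL32 (1.80 ± 0.33), an inflammatory cytokine, CXCL1 (1.75 ± 0.27), a neutrophil chemokine, and TNFSF15 (1.75 ± 0.25). SMARCD3, a subunit of chromatin remodelling complexes, fell with ADAR among the largest (-1.62 ± 0.35). The largest fitted fall was that of GTF2H2C_2, a near-identical copy of GTF2H2C, which had 461 counts over the control libraries and 0 over the ADAR1 siRNA libraries, at least 202-fold lower against a floor of 3 counts over the group. The counts of GTF2H2C_2, GTF2H2C and GTF2H2 summed differed by -0.05 on the log2 scale, so the value is uncertain. Adjusted p-values of these and the genes above lay between 0.00186 and 0.0485 by edgeR. Without control Ribo-seq replicate 2 the count was 77, without ADAR1 siRNA Ribo-seq replicate 1 it was 1868 and without replicate 2 it was 3415. Among 38 named genes called besides ADAR, 13 stayed called whichever single library was left out: CASP1, CCL2, COL5A1, CXCL1, CXCL3, CXCL8, DDIT3, GTF2H2C_2, IFIT1, IFIT3, IL32, OASL and TNFSF15. Leaving out control replicate 1 ended 12 of the 38 calls and leaving out control replicate 2 ended 25. IL32 stood at 1.12 without ADAR1 siRNA Ribo-seq replicate 1, and COL5A1 at 0.81 without replicate 2. Groups did not overlap for 56.3% of tested genes, against 33.3% by chance if all libraries varied alike. Here too the ADAR1 siRNA pair lay further apart (SD of log2 differences 0.452 against 0.365 in controls), which raises the share that chance gives.

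Of the 28 lists, 10 shifted in Ribo-seq with the preset correlation, 3 up and 7 down, and none with an estimated correlation, where the adjusted p was 0.639 for each of the 10. NF-kB targets and inflammatory cytokines were shifted up (median log2 0.79, 23 of 26 above 0, camera adjusted p = 2.94e-05, adjusted p = 0.639 with an estimated correlation). Of these, 9 rose among all genes (CXCL8, CXCL3, CXCL1, IL32, IL1A, CCL2, ICAM1, IL6 and BIRC3), 17 did not pass, and 14 rose and 1 fell adjusted over the list alone. Its median was 0.50 without ADAR1 siRNA Ribo-seq replicate 1. The interferon-stimulated list was shifted down (median -0.36, 50 of 65 below 0, camera adjusted p = 1.16e-07, adjusted p = 0.639 with an estimated correlation). IFIT1, IFIT3, OASL, IFI44, HERC5, IFIT2, TRIM5, RIGI and MX1 fell among all genes, 56 members did not pass, and 15 fell adjusted over the list alone. IFIT3 stood at -1.23 ± 0.18. Genes beyond the naming rule appear here and in the next lists as members of these counts. The list median was -0.34 in ADAR1 siRNA Ribo-seq replicate 1 and -0.36 in replicate 2, and -0.23 without control Ribo-seq replicate 2.

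Splicing factors and RNA-binding proteins had a median of -0.42 (47 of 53 below 0, camera adjusted p = 2.81e-08, adjusted p = 0.639 with an estimated correlation); 8 fell among all genes, with HNRNPK at -0.86 ± 0.15, HNRNPL at -0.80 ± 0.15 and the RNA helicase gene DDX5 at -0.99 ± 0.20, and 26 fell and 1 rose adjusted over the list alone. G1/S genes had a median of -0.35 (33 of 38 below 0, camera adjusted p = 1.36e-06, adjusted p = 0.639 with an estimated correlation). Of these 7 fell among all genes and 17 fell and 1 rose adjusted over the list alone, with the replication licensing genes CDC6 at -1.05 ± 0.19 and MCM4 at -1.01 ± 0.20 and the ribonucleotide reductase gene RRM2 at -0.68 ± 0.14. G2/M genes had a median of -0.28 (30 of 41 below 0, camera adjusted p = 0.000238, adjusted p = 0.639 with an estimated correlation); NUSAP1 (-0.87 ± 0.16), KIF11 (-0.85 ± 0.17), ECT2 (-0.71 ± 0.15) and CCNB1 fell, whereas MKI67, the gene of the proliferation marker Ki-67, rose by 0.91 ± 0.20, and 15 fell and 2 rose adjusted over the list alone. The G2/M median was -0.58 in ADAR1 siRNA Ribo-seq replicate 1 and -0.13 in replicate 2; it was -0.12 without replicate 1 and -0.63 without replicate 2. Translation factors had a median of -0.25 (32 of 41 below 0, camera adjusted p = 0.000108, adjusted p = 0.639 with an estimated correlation). EIF3C (-0.87 ± 0.18), EIF3D (-0.81 ± 0.17) and EEF1A1 fell among all genes, as did NPM1 (-0.66 ± 0.15), a list member known as a nucleolar histone chaperone and ribosome biogenesis protein, and 13 fell adjusted over the list alone; without ADAR1 siRNA Ribo-seq replicate 1 the median was -0.16.

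ER chaperones were shifted up in Ribo-seq (median 0.44, 22 of 23 above 0, camera adjusted p = 3.41e-05, adjusted p = 0.639 with an estimated correlation). CALR (0.66 ± 0.12), DNAJC3 (0.70 ± 0.15) and PDIA3 (0.58 ± 0.13), which encode folding factors of the ER lumen, rose among all genes, and 11 rose and 1 fell adjusted over the list alone. Mesenchymal and matrix genes were also shifted up (median 0.45, 33 of 39 above 0, camera adjusted p = 0.0011, adjusted p = 0.639 with an estimated correlation). The integrin genes ITGAV (0.99 ± 0.14) and ITGB1 (0.83 ± 0.14) rose with the collagen gene COL5A1 (1.29 ± 0.23), COL4A1 and LOXL2, while ANXA2 fell, and 17 rose and 2 fell adjusted over the list alone. This list lost its call without control Ribo-seq replicate 2 (camera adjusted p = 0.0584) or ADAR1 siRNA Ribo-seq replicate 2 (0.20, median 0.21). Glycolysis and hypoxia genes were shifted down (median -0.18, 24 of 35 below 0, camera adjusted p = 0.0105, adjusted p = 0.639 with an estimated correlation); HK2 (-1.03 ± 0.19), PFKM (-0.87 ± 0.18), PKM, PFKP and PGK1, all glycolytic enzymes, fell, P4HA1, a collagen hydroxylase, rose by 0.74 ± 0.14, and 11 fell and 2 rose adjusted over the list alone. Its call was lost without control replicate 2 (0.0556) or ADAR1 siRNA replicate 1 (0.0928), and its median was -0.49 without ADAR1 siRNA replicate 2. Luminal epithelial markers had a median of -0.26 (13 of 17 below 0, camera adjusted p = 0.0106, adjusted p = 0.639 with an estimated correlation), and the keratin genes KRT19 (-0.99 ± 0.15) and KRT8 (-0.96 ± 0.21) fell both among all genes and adjusted over the list alone, while KRT18 stood at -0.50 ± 0.17 (edgeR adjusted p = 0.109). Its call was lost without control replicate 1 (0.0914) or ADAR1 siRNA replicate 2 (0.758, median -0.15), and its median was -0.64 without ADAR1 siRNA replicate 1.

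The other 18 lists did not shift in Ribo-seq, with camera adjusted p-values from 0.0609 to 0.998. In the integrated stress response list (median 0.04) DDIT3 rose by 1.53 ± 0.26 and PPP1R15A by 0.92 ± 0.16, whereas the serine synthesis gene PHGDH stood at -1.01 ± 0.25 (edgeR adjusted p = 0.0542). In the double-stranded RNA sensing list (median -0.18) RIGI fell by 0.81 ± 0.17 on the log2 scale, while NLRP1 (-0.91 ± 0.24) and OAS3 (-0.63 ± 0.19) did not pass. Cytosolic ribosomal proteins had a median of 0.05, with RPLP2 at 0.51 ± 0.14, RPS4X at -0.60 ± 0.16 and RPSA at -0.59 ± 0.16, and 0 of 79 members passed by edgeR, where 16 had an unadjusted p under 0.05. Histones had a median of 0.02 over 38 members. Medians of the remaining lists were -0.31 for the ADAR family, -0.31 for the m6A machinery, -0.02 for mitochondrial ribosomal proteins, 0.28 for known recoding substrates, -0.03 for the transcription machinery, 0.15 for YAP and TEAD targets, 0.12 for the microRNA machinery, 0.11 for sterol synthesis, 0.09 for the mitochondrial genome, 0.15 for p53 targets and 0.05 for respiratory chain subunits, whose mean was -0.01. Basal or myoepithelial markers had a median of 0.23, endothelial markers 0.05 with a mean of -0.01, and immune markers -0.04 with a mean of 0.16.

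**Figure D2:**
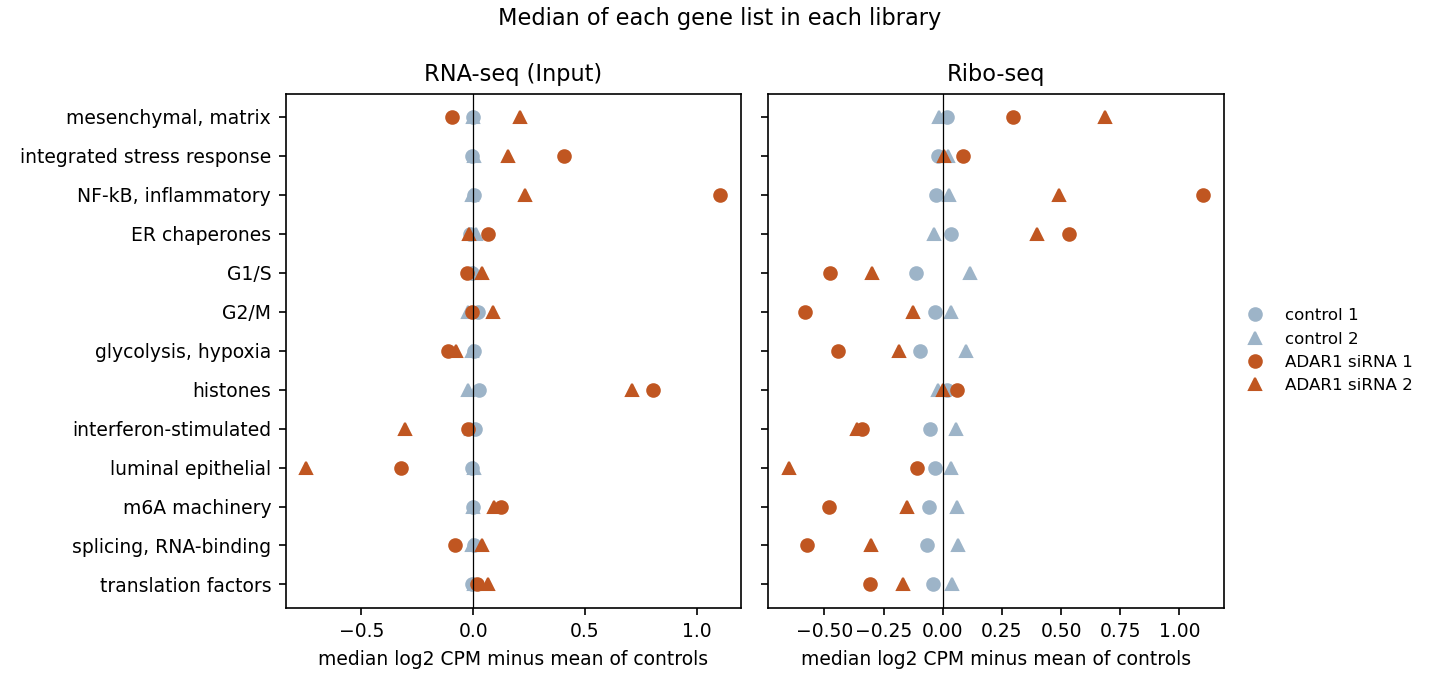
Median over the members of each gene list of log2 CPM minus the mean of the 2 control libraries (horizontal axes), in RNA-seq on the left and Ribo-seq on the right; circles are replicate 1, triangles replicate 2, blue control siRNA and orange ADAR1 siRNA. The lists are those that shifted in at least 1 comparison. The interferon-stimulated list lies at -0.34 and -0.36 in Ribo-seq but at -0.02 and -0.31 in RNA-seq, and the NF-kB list at 1.10 and 0.49 in Ribo-seq.

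Across the 11743 genes tested in both assays, fold changes of RNA and of footprints were weakly related (Pearson r = 0.239, Spearman rho = 0.156 across genes, which are not independent replicates), and 54.2% had the same sign. Without ADAR1 siRNA Ribo-seq replicate 2 the Pearson r was 0.156. The 2 comparisons shared no library. Of the genes called in Ribo-seq, 290 of 417 (69.5%) had the same sign in RNA. HDAC9, SEMA3C, TFPI and TNFSF15 rose in both assays, 4 genes where 0.169 would be expected of independent lists. CKB, ENTPD3 and G0S2 fell in both, 3 genes where 0.367 would be expected. SEMA3C encodes a secreted guidance protein and CKB the brain-type creatine kinase; they are named here as members of these counts, outside the naming rule.

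**Figure D3:**
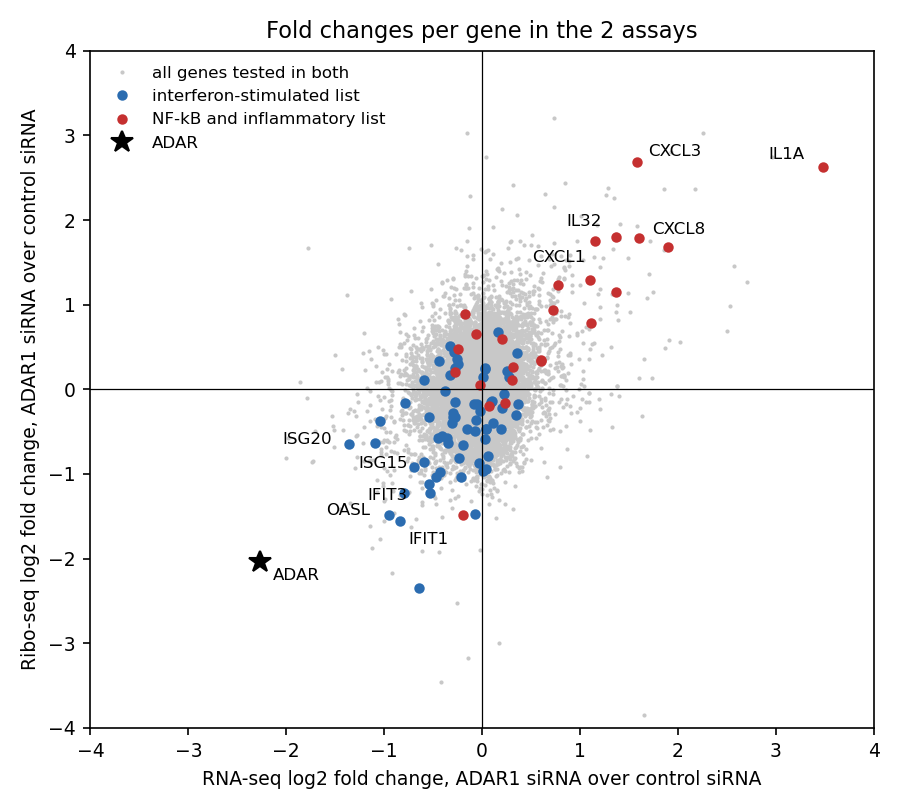
Log2 fold change of ADAR1 siRNA over control siRNA in RNA-seq (horizontal axis) against Ribo-seq (vertical axis); each point is 1 of 11739 genes, and 4 genes lie outside the axes. Blue points are the interferon-stimulated list, red points the NF-kB and inflammatory list, and the star is ADAR at -2.26 and -2.04.

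Translational efficiency, the footprints of a gene relative to its RNA, was compared next. Its folds are edgeR estimates from scaled counts, and the TPM means beside them need not give the same ratios. TMEM132A, a transmembrane protein gene, rose 2.33-fold: its RNA stood at 25.7 ± 0.279 TPM with control siRNA and 17.4 ± 0.326 TPM with ADAR1 siRNA, and its footprints at 6.69 ± 0.318 and 9.78 ± 0.887 TPM. TRAF6, an adaptor of Toll-like and interleukin 1 receptor signalling, fell 2.74-fold, with RNA at 8.07 ± 0.0948 and 10.6 ± 0.567 TPM and footprints at 27.6 ± 1.18 and 10.5 ± 2.88 TPM. H1-2 fell 2.44-fold, its footprints standing at 1862 ± 6.98 and 1607 ± 127 TPM while its RNA rose as above (mean ± SD, n = 2 libraries per group).

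By the edgeR interaction test, fitted without a replicate block, 6 of 12953 genes changed, 2 higher and 4 lower, with 2940 at an unadjusted p under 0.05. Log2 changes were 1.22 ± 0.16 for TMEM132A, -1.45 ± 0.20 for TRAF6 and -1.29 ± 0.16 for H1-2, with adjusted p-values from 0.0447 to 0.0456. Also called were FAM72D (2.43 ± 0.31) and GTF2H2C_2, both near-identical copies whose families, summed, differed by -0.02 and -0.05 in footprints, so their values are uncertain. The count was 0 without ADAR1 siRNA Input replicate 1 or replicate 2 (edgeR; 2207 and 2683 genes at an unadjusted p under 0.05, 0 by limma-voom, 372 and 684 by DESeq2). It was 1 without any single control library, which ended 5 of the 6 calls, 507 without ADAR1 siRNA Ribo-seq replicate 1 and 2252 without replicate 2. GTF2H2C_2, whose value is uncertain, was the gene that stayed called whichever control library was left out. Log2 changes from the interaction test over all libraries correlated with those of the authors' deposited translational efficiency across 10839 genes (r = 0.982). The number of calls depended on the design. With the replicate number as a block 448 genes were called, and with a block for each siRNA and number 1169. The labels do not say whether Input and Ribo-seq libraries of the same number came from the same lysate, so it stays open which design applies.

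In translational efficiency 10 of the 28 lists shifted with the preset correlation, 2 up and 8 down, and none did with an estimated correlation; the median of all genes was 0.09. The 2 lists shifted up were ER chaperones (median log2 0.44, 21 of 23 above 0, camera adjusted p = 0.000279, adjusted p = 0.609 with an estimated correlation) and mesenchymal and matrix genes (median 0.47, 29 of 40 above 0, camera adjusted p = 0.0329, adjusted p = 0.737 with an estimated correlation). Adjusted over the list alone, 10 ER chaperones and 4 matrix genes rose; examples were CALR (0.71 ± 0.16), PDIA4 (0.71 ± 0.17) and SDF2L1 (1.06 ± 0.30), and the collagen VI genes COL6A2 (1.01 ± 0.18) and COL6A1 (0.95 ± 0.23) with ITGA5 (0.80 ± 0.17). The mesenchymal and matrix list lost its call without control Input replicate 1, ADAR1 siRNA Input replicate 1, control Ribo-seq replicate 2 or ADAR1 siRNA Ribo-seq replicate 2 (camera adjusted p = 0.0641, 0.308, 0.441 and 0.531). Its median was 0.09 without ADAR1 siRNA Input replicate 1 and 0.20 without ADAR1 siRNA Ribo-seq replicate 2. Of the lists shifted down, the m6A machinery had a mean of -0.25 (median -0.58, 13 of 21 below 0, camera adjusted p = 0.0101, adjusted p = 0.508 with an estimated correlation), in which 11 fell and 2 rose adjusted over the list alone. The reader genes YTHDC2 (-1.02 ± 0.22) and YTHDF3 (-0.78 ± 0.18) stood opposite the demethylase gene ALKBH5 (0.85 ± 0.18). G1/S genes had a median of -0.40 (32 of 38 below 0, camera adjusted p = 9.9e-07, adjusted p = 0.576 with an estimated correlation), and 17 fell and 1 rose adjusted over the list alone, with CDC6 at -1.10 ± 0.21 and DTL at -1.03 ± 0.22, beside MCM4; the median was -0.26 without ADAR1 siRNA Ribo-seq replicate 1. Splicing factors had a median of -0.37 (41 of 53 below 0, camera adjusted p = 3.86e-08, adjusted p = 0.508 with an estimated correlation), with 20 falling and 1 rising adjusted over the list alone, among them HNRNPK (-0.78 ± 0.17), SF3B3 (-0.82 ± 0.20) and DDX5 (-0.98 ± 0.23).

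G2/M genes had a median translational efficiency change of -0.34 (31 of 41 below 0, camera adjusted p = 0.000116, adjusted p = 0.609 with an estimated correlation); 8 fell and 1 rose adjusted over the list alone, with KIF11 at -0.99 ± 0.18, NUSAP1 at -0.79 ± 0.18 and MKI67 at 0.95 ± 0.24. The G2/M median was -0.14 without ADAR1 siRNA Ribo-seq replicate 1 and -0.58 without replicate 2. Translation factors had a median of -0.25 (32 of 41 below 0, camera adjusted p = 5e-06, adjusted p = 0.508 with an estimated correlation), and 13 fell adjusted over the list alone, among them EIF2S1 (-0.69 ± 0.16), EIF3D (-0.79 ± 0.18) and the nucleolar protein gene NPM1 (-0.76 ± 0.18). ATF4 targets had a median of -0.22 (21 of 34 below 0, camera adjusted p = 0.0291, adjusted p = 0.622 with an estimated correlation); 9 fell and 4 rose adjusted over the list alone, with ASNS at -1.20 ± 0.31, AARS1 at -0.91 ± 0.23 and PSAT1 at -0.74 ± 0.17. Histones had a median of -0.18 (25 of 40 below 0, camera adjusted p = 0.0101, adjusted p = 0.508 with an estimated correlation). Adjusted over the list alone 6 fell, and the identical copies H4C14 and H4C15 each stood at -1.31 ± 0.32. The low Input levels of histones given above limit these values and that of H1-2. The interferon-stimulated list had a median of -0.18 (43 of 65 below 0, camera adjusted p = 0.0146, adjusted p = 0.622 with an estimated correlation), and 6 fell and 5 rose adjusted over the list alone, with TRIM5 at -0.95 ± 0.21, TAP1 at 0.86 ± 0.22 and LGALS3BP at 0.65 ± 0.15. Apart from H1-2, no list member passed among all genes. ATF4 targets lost their call without control Input replicate 1, ADAR1 siRNA Input replicate 1, control Ribo-seq replicate 2 or ADAR1 siRNA Ribo-seq replicate 2 (camera adjusted p = 0.0604, 0.194, 0.0697 and 0.299). Their median was -0.44 without ADAR1 siRNA Input replicate 2, -0.34 without ADAR1 siRNA Ribo-seq replicate 1 and -0.07 without ADAR1 siRNA Ribo-seq replicate 2. Interferon-stimulated genes lost theirs without ADAR1 siRNA Input replicate 1, control Ribo-seq replicate 2 or ADAR1 siRNA Ribo-seq replicate 2 (0.194, 0.176 and 0.180), and histones without ADAR1 siRNA Input replicate 2, control Ribo-seq replicate 1 or ADAR1 siRNA Ribo-seq replicate 2 (0.0627, 0.0623 and 0.151). The interferon-stimulated median was -0.28 without control Input replicate 1, -0.33 without ADAR1 siRNA Input replicate 2 and -0.11 without control Ribo-seq replicate 2. The histone median was -0.31 and -0.34 without control Input replicate 1 and 2, -0.39 and -0.09 without ADAR1 siRNA Input replicate 1 and 2, and -0.07 without control Ribo-seq replicate 1.

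The other 18 lists did not shift in translational efficiency, with camera adjusted p-values from 0.0577 to 0.770. The double-stranded RNA sensing list had a median of 0.00 with TICAM1 at 1.05 ± 0.24 and TRIM25 at -0.52 ± 0.20. Cytosolic ribosomal proteins had a median of 0.06 with RPSA at -0.70 ± 0.21, RPS4X at -0.69 ± 0.21 and FAU at 0.57 ± 0.18. Medians of the remaining lists were 0.01 for the ADAR family, 0.34 for NF-kB targets, -0.12 for glycolysis and hypoxia, -0.07 for the transcription machinery, 0.49 for known recoding substrates, 0.20 for the mitochondrial genome, 0.05 for mitochondrial ribosomal proteins, 0.18 for the microRNA machinery, -0.06 for p53 targets, 0.06 for sterol synthesis, 0.11 for respiratory chain subunits and 0.14 for YAP and TEAD targets. Markers of other cells had medians of 0.53 (basal or myoepithelial), 0.56 (immune), 0.39 (endothelial) and 0.16 (luminal epithelial). Camera's direction opposed the sign of the median for mitochondrial and cytosolic ribosomal proteins, double-stranded RNA sensing, sterol synthesis, luminal markers and YAP and TEAD targets.

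Several genes named above have paralogs or pseudogenes of nearly the same sequence, between which estimated counts could be split: CST4, the CXCL chemokines, EIF3C, the keratins, the histones, EEF1A1, NPM1 and the ribosomal protein genes. Their values are uncertain to that extent.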

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

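The comparison of lists with genes of their own chromosome, that of chromosomes within the lists, and that of the weaker replicate with the controls were chosen after results had been seen. Each of the results below is a difference between the siRNA effect in Ribo-seq and that in RNA-seq, tested as an interaction.

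For single genes the change in translational efficiency was -1.29 for H1-2, 1.22 for TMEM132A and -1.45 for TRAF6 on the log2 scale. FAM72D had a value of 2.43, and GTF2H2C_2 a fitted value of -11.87 that depends on the prior count because both ADAR1 siRNA Ribo-seq libraries were at 0. Both have near-identical copies, and the counts of each family summed differed by -0.02 and -0.05 in Ribo-seq.

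Among gene lists the median change was -0.40 for G1/S genes, -0.37 for splicing factors, -0.34 for G2/M genes, -0.25 for translation factors, -0.58 for the m6A machinery, -0.22 for ATF4 targets, -0.18 for histones and -0.18 for interferon-stimulated genes. It was 0.44 for ER chaperones and 0.47 for mesenchymal and matrix genes. All 10 calls were lost with an estimated correlation, where the smallest adjusted p was 0.508.

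Shifts in translational efficiency were not particular to these lists. Of 32 gene families defined by symbol after results had been seen, 23 were also shifted with the preset correlation, 12 up and 11 down. With an estimated correlation 0 were. The shift between lists was weighed against 3 technical explanations, and others were not tested. Removing the trend on effective length left more than 50% of the median in 10 of 10 lists, which argues against transcript length as the whole cause. In 8 of 10 lists the weaker ADAR1 siRNA replicate lay 2.93 to 20.6 times as far from the control mean as the controls, on the side of the shift. In 9 of 10 both replicates kept the sign. This does not decide on a single aberrant library, which stays open. The lists were chosen by their shift in the same libraries, and the ADAR1 siRNA replicates varied more than the controls. The ratio was -0.38 for histones and 0.47 for interferon-stimulated genes. Medians without ADAR1 siRNA Ribo-seq replicate 2 were 0.20 for mesenchymal and matrix genes and -0.07 for ATF4 targets. Each of these 4 lists lost its call without 1 ADAR1 siRNA library. GC-dependent recovery could not be settled without GC content. Changes were higher by 0.12 ± 0.019 (bootstrap SE) on GC-rich than on AT-rich chromosomes, which met the criterion set beforehand for GC-dependent recovery. Against the control mean the difference was 0.15 in ADAR1 siRNA replicate 1 and 0.09 in replicate 2, and between the controls it was -0.02. Among members of these lists it was of like size but imprecise (0.11 ± 0.12), so it could not be tied to the list shifts. The chromosome difference was larger in RNA (-0.18 ± 0.00897) than in footprints (-0.04 ± 0.0141), and the list shifts in RNA were not set against it. In translational efficiency 10 of 10 lists kept their sign and more than 50% of their median against genes of their own chromosome. Medians of the autosomes and X ran only from 0.004 to 0.195, too narrow a range to take 50% from any of these lists. That comparison therefore could not decide on GC-dependent recovery. A change in translation after ADAR1 siRNA stays open beside these explanations, as a hypothesis.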

How the results depend on the processing

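Leaving out both ADAR1 siRNA libraries of 1 replicate number, and fitting all 8 libraries together for the gene lists, were chosen after the data were examined. No gene called in RNA, Ribo-seq or translational efficiency changed sign under any alternative. The causes of the differences below were not tested.

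Against 32 genes in RNA, 11 were called with upper-quartile scaling (5 higher and 6 lower, against 10 and 22), 95 with no filter, 73 with a mean count of at least 50, 449 with DESeq2 and 14 with all 8 libraries in 1 fit. Against 425 in Ribo-seq, 1693 were called with no filter, 978 with DESeq2, 250 with limma-voom and 1936 with all 8 libraries. Against 6 in translational efficiency, 854 were called with no filter, 2 with a mean count of at least 50, 982 with DESeq2 and 0 with limma-voom (2885 at an unadjusted p under 0.05). With 1 library left out, counts ran from 0 to 5420 in RNA, from 77 to 3415 in Ribo-seq and from 0 to 2252 in translational efficiency. Without both ADAR1 siRNA libraries of replicate 1 the last was 1039, and without those of replicate 2 it was 3208. Higher calls were 52.9% in Ribo-seq, 63.9% with upper-quartile scaling and 40.0% with DESeq2.

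ADAR in RNA passed with no filter (-2.26), with a mean count of at least 50 (-2.26) and with DESeq2 (-2.26), and ran from -2.94 to -1.81 with 1 library left out. In Ribo-seq it did not pass with DESeq2 (-2.06). Its translational efficiency changed from 0.25 to -0.58 without both ADAR1 siRNA libraries of replicate 2, and then passed; with 1 library left out it ran from -1.16 to 0.94 and did not pass.

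Of 5, 10 and 10 lists shifted in RNA, Ribo-seq and translational efficiency, 0, 0 and 0 were called with an estimated correlation. Fry called 1, 0 and 1 lists. In RNA that was histones (fry adjusted p = 0.0398). In translational efficiency it was basal or myoepithelial markers (fry adjusted p = 0.00878), which camera had not called (camera adjusted p = 0.0577), and none of the lists that camera called. With 1 library left out the number in RNA ran from 5 to 9.

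With the replicate number as a block, 1095 genes were called in RNA, 2102 in Ribo-seq and 448 in translational efficiency, or 1169 with a block for each siRNA and number, and ADAR in RNA stood at -2.35 and passed. Replicate differences correlated at 0.39 between ADAR1 siRNA Input and Ribo-seq and between -0.02 and 0.06 in the other 5 pairs of groups. No effect shared by replicate number was therefore visible across siRNAs. This cannot show whether samples of the same number were handled as pairs, which the labels do not say.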

Other observations

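The gene families in the next paragraph, defined by symbol, and the tests of a single aberrant library in Ribo-seq alone and of library preparation were chosen after results had been seen.

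Of 32 gene families, 21 were shifted in Ribo-seq (11 up and 10 down) with camera's preset correlation, and 0 were with an estimated correlation, so the families named here are examples. HLA genes were higher (median log2 0.79, 16 of 16 above 0, camera adjusted p = 2.48e-07, adjusted p = 0.395 with an estimated correlation), and 7 rose among all genes by edgeR; in RNA their median was 0.07. HLA genes have similar sequences, so single members are uncertain. Glycosyltransferases had a median of 0.47 (9 rose), lysosomal enzymes, cathepsins and genes of like symbol 0.48 (6 rose), ADAM proteases 0.49 (4 rose), integrins 0.46 (4 rose) and solute carriers 0.26 (4 of 220 rose). DEAD- and DEAH-box helicases were lower (median -0.52, 4 of 49 above 0, camera adjusted p = 2.13e-10, adjusted p = 0.395 with an estimated correlation), and 8 fell. Subunits of the chaperonin CCT had a median of -0.57 (3 of 9 fell), heat shock proteins -0.57 (5 fell, among them HSPD1, the mitochondrial chaperonin), nucleoporins -0.46 (2 fell) and tRNA synthetases -0.34 (2 fell). In RNA only zinc finger genes were shifted (median 0.18 over 450 genes, camera adjusted p = 3.32e-07, adjusted p = 0.843 with an estimated correlation). The median of all genes in Ribo-seq was 0.05, 0.01 with RLE and 0.09 with upper-quartile scaling.

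The fall of the interferon-stimulated list was weighed against 2 technical explanations. Scaling was not tested by the 3 scalings tried, since a scaling factor moves the list and all genes alike: the list median minus that of all genes was -0.26 in RNA under each. A single aberrant library is argued against in Ribo-seq, where at least 69.2% of members lay below both controls in each ADAR1 siRNA library; over both assays the lowest share was 50.8%, in Input replicate 1, so in RNA it stays open. Whether the ADAR1 siRNA or the control siRNA cells moved is also open, since 0 libraries came from untransfected cells.

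The ADAR1 siRNA replicates lay further apart than the controls did. In Input the mean Poisson chi-square per gene was 19 between them and 1.92 between the controls. The replicate differences of Input and Ribo-seq correlated at 0.39 across genes, which are not independent replicates. This argues against differences in the preparation of single libraries as the whole cause. Preparation as the cause of the part that did not recur in the other assay stays open. A graded knockdown stays open: ADAR was lower in replicate 1 in both assays, and the Input fold changes of both replicates correlated at 0.475 across genes, but with 2 replicates it cannot be told apart from other differences between them. Several Input lists were not a weaker copy in replicate 2: medians in replicates 1 and 2 were -0.11 and 0.15 for cytosolic ribosomal proteins, -0.21 and 0.08 for the mitochondrial genome, -0.02 and -0.31 for interferon-stimulated genes and -0.32 and -0.74 for luminal markers.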
